A study of Mus musculus with 36 samples.

How the data were processed

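Gastrocnemius muscle of WT mice and of mice with a liver-specific deletion of Bmal1 was taken at 6 zeitgeber times, with 3 biological replicates per genotype and time (12 groups, 36 libraries). RNA was purified on columns, and polyadenylated RNA was captured on poly-T beads and copied from random hexamers. The values used here are FPKM per gene symbol, deposited by the authors in 1 table of 24319 symbols for all 36 libraries. The processing notes name FastQC 0.11.8, the aligner STAR and the genome builds mm10 and GRCm39. The tool that computed FPKM, its annotation, any scaling between libraries and the build behind the table are not given in the sources used here. No reads were aligned for the present values. The table held 0 in every library for 5577 symbols and none of the 13 mitochondrially encoded mRNAs, so the mitochondrial transcripts described are those of nuclear genes.

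Read totals are not given in the sources used here. A relative depth per library was computed from the FPKM worth of 1 read in 3864 genes of mean FPKM below 0.3: the most frequent ratio between each pair of libraries was taken, and the ratios were combined by least squares, with 93.8% of pairs within 0.05 on the log2 scale of the combined depths. The deepest library was 1.73 times as deep as the shallowest. FPKM sums ran from 518559 to 830136, the 10 highest genes took 26.7% to 31.9% of the sum, 10367 to 11302 genes reached 1 FPKM, and the median over tested genes ran from 7.13 to 7.83 FPKM. No 2 libraries held identical values.

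Values were log2(FPKM + 1), and the 10837 genes with a mean of at least 1 FPKM over the 36 libraries were tested. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust) in a fit of 12 group means with 24 residual degrees of freedom. The contrasts were the mean of the 6 differences between Bmal1hep-/- and WT, the difference at each time, and an F test of the 5 contrasts between times. Rhythms were tested in a fit with a mean, a cosine and a sine of 24 h period per genotype and 30 residual degrees of freedom, by F tests of the cosine and sine terms in WT, in Bmal1hep-/-, in their mean and in their difference. Amplitude is the distance from the mean to the peak of the cosine on the log2 scale. The SE of amplitude and peak time came from the delta method. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The period was fixed, since 6 times over 1 day cannot estimate it.

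Of 55 gene lists fixed before the data were examined, 50 had at least 3 tested members. Lists were compared between genotypes with limma's camera at a preset inter-gene correlation of 0.01, beside the result with an estimated correlation, and among rhythmic genes by Fisher's exact test against all genes tested, adjusted over the lists. The groups, tests, lists, alternatives not named below as chosen later and the rule for naming genes were also set before the data were examined. The rule names Arntl and the core clock genes, the 10 genes of largest amplitude for each rhythm test and the genes of largest change past the threshold for each genotype test. Where fewer than 5 genes passed, it names the 10 of smallest p as values, and for each list described up to 4 members of smallest p. Predicted genes were counted and not named. A few genes that the rule names are not reported here.

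The median ratio of amplitudes and the median peak difference were tested by 100 draws that swapped genotypes within time, counts of genes by other splits of the samples, and correlations between libraries by 1e+05 permutations, adjusted over 3 relations. Alternatives were a pseudocount of 0.1, no filter on level, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization, the replicate number as a block, array weights, fits on fewer libraries, time as a factor, selection among 5 models by BIC, a minimum amplitude of 0.25 and leaving out each library in turn. Chosen after seeing the data were removal of a trend with transcript length, the leaving out of 6 libraries that stood apart, and leave-one-out fits for lists. Transcript lengths came from GENCODE M21, which held 23284 of the 24319 symbols and 10466 (96.58%) of the tested genes; it was used for lengths alone, and a build other than the one used for FPKM would shift them. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

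The tests were tried on simulated data made by shuffling the residuals of whole libraries, in 20 draws with 200 changed genes of 10837. A log2 difference of 0.5 over all times was recovered for 94.7% of changed genes, and 0.25 for 62.5%; at ZT12 a difference of 1 was recovered for 89.0% and 0.5 for 40.4%. An amplitude of 0.5 was recovered for 94.2% in WT and 92.3% in Bmal1hep-/-, and a difference of 0.5 in rhythm for 74.8%. At a size of 0.25 these were 53.9%, 51.4% and 17.8%. Differences between times of 1 were recovered for 68.6%. False calls made up 4.13% of calls over all times, 2.44% between times, 2.12% for rhythms in Bmal1hep-/- and 2.4% for differences in rhythm. They made up 31.9% for rhythms in WT and 35.7% at ZT12, where single draws reached 88.8% and 90.8% and the medians over draws were 2.1% and 0.691%. Residuals were shuffled over both genotypes, so the rates for rhythms in WT and in Bmal1hep-/- do not compare the genotypes.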

Results

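Polyadenylated RNA of gastrocnemius muscle was sequenced from wild-type (WT) mice and from mice in which Bmal1, a core gene of the circadian clock, was deleted in the liver (Bmal1hep-/-). Muscle was collected at zeitgeber time (ZT) 0, 4, 8, 12, 16 and 20, with 3 biological replicates in each of the 12 groups and 36 libraries in all. The series title asks how the liver clock bears on transcriptional rhythms and mitochondrial function in skeletal muscle, and the comparisons below describe the muscle mRNAs that bear on that question. Total read counts are not given in the sources used here, so the absolute depth of each library is unknown. The steps between low values gave a relative depth: the shallowest library had 57.9% of the depth of the deepest, with a median of 69.1% in WT and 73.7% in Bmal1hep-/-. Replicates of the same group correlated across genes with Pearson's r of 0.96 to 0.992, and Bmal1hep-/- libraries lay farther from their group means than WT libraries (root mean square 0.29 against 0.23 on the log2 scale).

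A few libraries stood apart in the mRNAs of other cell types or in the balance of short and long transcripts. WT ZT8 replicate 3 held the hepatocyte markers at 3.89 above the mean of all libraries on the log2 scale. Bmal1hep-/- ZT4 replicate 1 and Bmal1hep-/- ZT20 replicate 3 held the adipocyte markers at 2.69 and 2.08 above it. In Bmal1hep-/- ZT12 replicate 2 and Bmal1hep-/- ZT8 replicate 2, levels fell with transcript length across genes, with Spearman's rho of -0.569 and -0.449. They rose with length most in Bmal1hep-/- ZT8 replicate 1 (0.405), Bmal1hep-/- ZT20 replicate 2 (0.375) and Bmal1hep-/- ZT20 replicate 3 (0.338). The next largest falls with length were in WT ZT20 replicate 3 (-0.402) and WT ZT16 replicate 3 (-0.389). Rn45s, the precursor of ribosomal RNA, chosen here after its values were seen, stood at 2206 to 2639 FPKM in WT and 4025 to 5184 FPKM in Bmal1hep-/- at ZT0, and at 12530 FPKM in Bmal1hep-/- ZT8 replicate 2. Its log2 difference was 0.55 ± 0.16 (SE) over all times (adjusted p = 0.28 in limma), 0.99 at ZT0, 0.72 at ZT4, 1.16 at ZT8 and 1.15 at ZT12, and -0.19 at ZT16 and -0.55 at ZT20, none past the threshold. In Bmal1hep-/- ZT16 replicate 3, Acta1, the skeletal actin gene, was listed at 0 FPKM, against a median of 32432.1 FPKM over all libraries. The 6 libraries named for marker levels, for the falls of -0.569 and -0.449 or for missing Acta1 are referred to below as the libraries that stood apart. This choice was made after the data were seen.

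The mRNAs of the muscle clock cycled in both genotypes with like amplitudes and peak times. Arntl, which encodes BMAL1, peaked near the end of the night and was lowest at ZT12. In WT muscle it stood at 16.1 ± 1.35 FPKM (SD, n = 3) at ZT0, 11.5 ± 2.64 at ZT4, 2.86 ± 0.45 at ZT8, 2.05 ± 0.22 at ZT12, 6.01 ± 1.18 at ZT16 and 11.7 ± 1.44 at ZT20. In Bmal1hep-/- muscle it stood at 18.01 ± 0.304, 8.83 ± 1.55, 3.67 ± 1.23, 1.87 ± 0.373, 5.69 ± 0.437 and 13.1 ± 1.59 FPKM at the same times. The deletion was made in liver, so the level of Arntl in muscle is no check of it. Of the core clock list, 18 of 19 members were expressed above the filter (Npas2 was not), and 16 passed the test of a 24 h rhythm in each genotype, the same 16 in both. Rora, a nuclear receptor that activates clock genes, did not pass, with an adjusted p of 0.154 in WT and 0.729 in Bmal1hep-/-. Nr1d1, which encodes the repressor REV-ERBα, peaked at 5.03 ± 0.246 h (SE) in WT and 4.86 ± 0.229 h in Bmal1hep-/-. The clock output factor Dbp peaked at 9.93 and 9.87 h, the period gene Per3 at 10.7 and 10.2 h, and the repressor Nfil3 at 20.0 and 19.9 h. Over the 16 genes the peak times differed by a median of 0.18 h and at most by 0.936 h, in Clock, and the ratio of amplitudes ran from 0.688 to 1.47. limma called a difference in rhythm for 0 of the 18 genes at an adjusted p under 0.05, adjusted over all genes or adjusted over the list alone, where the smallest adjusted p was 0.884, and 0 had an unadjusted p under 0.05. The 95% interval of the amplitude difference held 0 for all 16, as in Arntl (-0.20 to 0.26 on the log2 scale). As a list the core clock genes did not differ in level between genotypes (adjusted p = 0.686), and the median (-0.0094), the mean (0.017) and the direction of the test (up) differed in sign.

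**Figure D1:**
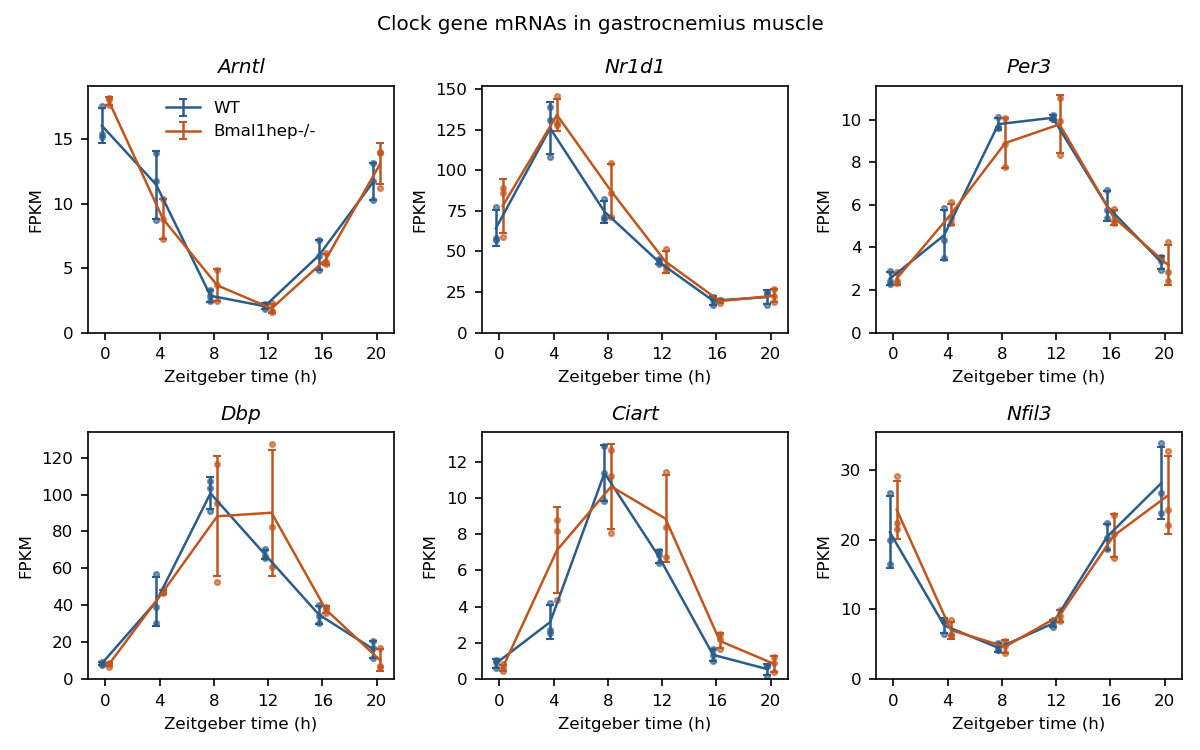
Level of 6 clock genes in FPKM (vertical axes, from 0) against zeitgeber time in hours, with a point per library, lines through the group means and bars of 1 SD (n = 3). WT and Bmal1hep-/- curves rise and fall at similar times, as in Arntl, which stood at 16.1 and 18.01 FPKM at ZT0 and at 2.05 and 1.87 FPKM at ZT12. Mean Dbp was 100.7 and 67.7 FPKM at ZT8 and ZT12 in WT, and 88.3 and 90.2 FPKM in Bmal1hep-/-.

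Daily rhythms beyond the clock genes were compared next, which addresses whether loss of the liver clock changes the rhythmic transcripts of muscle. A 24 h rhythm was called for 654 of 10837 tested genes in WT and for 593 in Bmal1hep-/-, and 353 genes were called in both, where 35.8 would be shared by independent sets. These counts used a spread per gene that was shared by both genotypes. With only the 18 libraries of each genotype, and so its own spread, the counts were 985 and 320. With time as a factor they were 334 and 335, by BIC 2419 and 2361, and with an amplitude of at least 0.25 they were 376 and 360. With array weights 1388 genes were called in WT, and without the 6 libraries that stood apart 383 were called in Bmal1hep-/-. Clock genes and their close outputs were among those of largest amplitude. In WT and Bmal1hep-/- the amplitudes were, on the log2 scale, 1.58 ± 0.15 and 1.84 ± 0.15 (SE) for Dbp, 1.53 and 1.59 for the clock repressor Ciart, 1.30 and 1.39 for Nr1d1, 1.28 and 1.31 for Arntl, 1.23 and 1.21 for Nfil3, and 1.19 and 1.31 for Per1. Metabolic genes had large amplitudes too. Pfkfb3, whose enzyme sets the level of fructose 2,6-bisphosphate and so the rate of glycolysis, had amplitudes of 1.24 ± 0.21 and 1.19 ± 0.21 and peaked at 6.0 and 5.59 h. Pnpla3, a lipid hydrolase, had amplitudes of 1.07 and 1.11 and peaked at 20.4 and 20.5 h. Slc25a30, a mitochondrial carrier, had amplitudes of 1.01 and 1.01, and the arrestin-family gene Arrdc2 had 1.41 and 1.33. Of the WT rhythms with an amplitude of at least 0.5, 80 of 98 were also called in Bmal1hep-/-, and 72 of 79 the other way.

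Among the 10 largest WT amplitudes, Chac1 and Alb were not called in Bmal1hep-/-. Chac1, a glutathione-degrading enzyme of the amino acid stress response, had amplitudes of 1.28 ± 0.31 in WT and 1.13 ± 0.31 in Bmal1hep-/- (adjusted p = 0.0265 and 0.07) in limma. The test of their difference gave an adjusted p of 0.974 in limma. The WT call of Chac1 was lost in 5 of 36 fits that left out 1 library, with an adjusted p of 0.0827 without WT ZT0 replicate 2. Alb, the albumin gene of hepatocytes, had amplitudes of 1.29 ± 0.28 in WT and 0.34 ± 0.28 in Bmal1hep-/- (adjusted p = 0.00948 and 0.779). Its difference in rhythm had an unadjusted p of 0.00144 and an adjusted p of 0.913, and its level was 30.2 FPKM in WT ZT8 replicate 3, a library that stood apart.

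Besides the core clock list, the lists of glucocorticoid targets, of shared clock outputs and of atrophy and FOXO targets were enriched among rhythmic genes in both genotypes, by Fisher's exact test against all genes tested. Glucocorticoid targets had 13 of 18 members called in WT (adjusted p = 2.03e-11) and 11 in Bmal1hep-/- (6.74e-09), 10 of them in both. Glul, which encodes glutamine synthetase, peaked at 15.3 and 16.2 h with amplitudes of 0.76 and 0.78, and Tsc22d3, which encodes GILZ, peaked at 16.1 and 15.7 h. Outputs that clocks of many tissues share had 10 of 14 members called in WT (8.02e-09) and 8 in Bmal1hep-/- (2.87e-06), among them the deubiquitinase Usp2 (amplitudes 0.66 and 0.70), the tetraspanin Tspan4 (0.62 and 0.66) and Coq10b, a gene of coenzyme Q function (0.73 and 0.79). Amplitudes were larger in Bmal1hep-/- in these 3, while over all 14 members the median log2 ratio of amplitudes, Bmal1hep-/- over WT, was -0.22 (permutation p = 0.04, 0.429 after adjustment over the 50 lists). The list of muscle atrophy and FOXO targets had 9 of 22 members called in WT (3.07e-05) and 6 in Bmal1hep-/- (0.00766). Its members included Klf15, a regulator of amino acid use (0.36 and 0.26), and Pik3ip1, an inhibitor of PI3 kinase (0.39 and 0.24). The call of that list in Bmal1hep-/- was kept in 23 of 36 fits without 1 library and had an adjusted p of 0.854 without Bmal1hep-/- ZT0 replicate 1.

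Polyamine and amino acid transport had 6 of 16 members called in WT (adjusted p = 0.00224) and 4 in Bmal1hep-/- (0.0681, not past the threshold), the same 4 in both. Proteasome genes had 1 of 30 called in WT (adjusted p = 1) and 0 in Bmal1hep-/- (0.929), and autophagy and lysosome genes 2 of 20 (0.815) and 0 (0.969). Branched-chain amino acid catabolism had 0 of 18 in both (1 and 0.969). The 4 shared transport genes were Glul, the arginine transporter Slc7a2 (amplitudes 0.55 and 0.43) and the neutral amino acid transporters Slc38a2 (0.55 and 0.60) and Slc38a4 (0.47 and 0.58). Endothelial markers had 4 of 10 members called in WT (0.0172) and 1 in Bmal1hep-/-, with peaks of the VEGF receptor Kdr at 1.57 and 0.837 h. This call was kept in 28 of 36 fits and had an adjusted p of 0.0967 without WT ZT8 replicate 2. Myogenic regulators and satellite cell genes had 5 of 11 members called in Bmal1hep-/- (0.00169) and 2 in WT, Myod1, the myogenic master regulator (0.82 in WT and 0.77 in Bmal1hep-/-), and the satellite cell proteoglycan Sdc4 (0.57 and 0.48). PPAR and fasting targets had 6 of 16 members called in Bmal1hep-/- (0.00163) and 1 in WT, as in amplitudes in WT and Bmal1hep-/- of 0.26 and 0.42 for the thioesterase Acot2, 0.30 and 0.40 for the uncoupling protein Ucp3, and 0.33 and 0.30 for the carnitine palmitoyltransferase Cpt1a. Without the 6 libraries that stood apart, 2 PPAR and fasting targets were called in Bmal1hep-/- (0.481), 1 atrophy and FOXO target was (1), and 3 myogenic genes were (0.0487). In glycolysis, which was not enriched (0.119 in WT and 0.0746 in Bmal1hep-/-), the same 4 genes were called in both genotypes: Pfkfb1, Pfkfb3, Pfkfb4 and the hexokinase Hk2. No member of the lists of complex I, complexes II and III, complex IV or ATP synthase was called in either genotype.

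The test of the difference itself called no change of rhythm, though it had little power for small ones. In the simulated data a difference of 0.25 was recovered for 17.8% of changed genes. The median amplitude of called genes was 0.275 in WT and 0.279 in Bmal1hep-/-. Selection by BIC, an alternative that does not control false calls, chose a model with unlike rhythms for 1029 genes. Of these, 514 were given a rhythm in WT only, 456 in Bmal1hep-/- only and 59 a different rhythm in each genotype. Swaps of genotype were not tried with BIC. limma gave 0 genes at an adjusted p under 0.05 (smallest 0.913) and 435 at an unadjusted p under 0.05, where 542 would be given by chance. Over the 894 genes rhythmic in either genotype limma gave 0, with 115 at an unadjusted p under 0.05 against 44.7 by chance. That excess is no independent evidence, since genes chosen as rhythmic in 1 genotype tend to differ from the other. Among the 10 genes of smallest p, given as values and not as changes, were the pseudogene Oaz1-ps, Mrps22, Nup35, Serbp1, Mcoln1, Sgsm3, Lsm2, Tysnd1 and Alb, all with an adjusted p of 0.913 in limma. Mcoln1, the lysosomal calcium channel, had amplitudes of 0.20 in WT and 0.14 in Bmal1hep-/- and peaks at 14.7 and 7.94 h, and Mrps22, a mitochondrial ribosomal protein, had 0.096 and 0.19 and peaks at 21.3 and 11.6 h. Leaving out WT ZT16 replicate 3 brought 1 gene past the threshold, Oaz1-ps (adjusted p = 0.0378). Adjusted over the list alone, 3 of 5 hepatocyte markers and 1 of 74 mitochondrial ribosome genes differed, and 0 genes of the other lists did. Of the 301 genes called in WT but not in Bmal1hep-/-, 143 had an unadjusted p under 0.05 in Bmal1hep-/-, and of the 240 called the other way 120 did in WT.

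Amplitude and timing were also compared over the 1346 genes with a rhythm in the mean of both genotypes. The median log2 ratio of amplitudes, Bmal1hep-/- over WT, was -0.0038 (2-sided permutation test that swapped genotypes within time, 100 draws, p = 0.97), with 676 genes larger in WT and 670 larger in Bmal1hep-/-. The draws of that test spanned -0.18 to 0.15, and the ratio was 0.083 without Bmal1hep-/- ZT8 replicate 1 and -0.072 without Bmal1hep-/- ZT12 replicate 2. Peaks were a median of -0.364 h apart, earlier in Bmal1hep-/- (permutation p = 0.21, draws from -0.772 to 0.727 h). Of the 353 genes called in both genotypes, 314 (88.95%) peaked within 2 h of each other, and the largest difference was 4.37 h. Among called genes, 146 in WT and 170 in Bmal1hep-/- peaked from 20 to 24 h. From 0 to 4 h there were 136 and 80, and from 8 to 12 h 120 and 124. The difference between these counts was not tested.

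**Figure D2:**
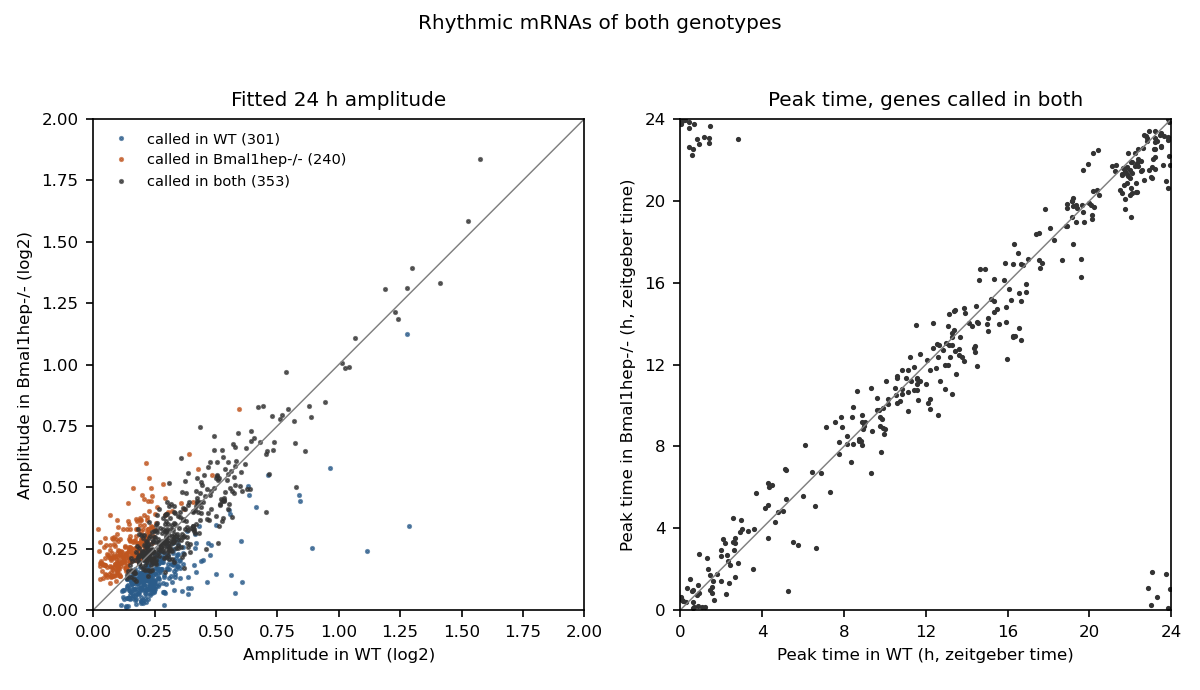
Left, fitted 24 h amplitude (log2) in WT (horizontal) and Bmal1hep-/- (vertical), a point per gene called in WT (301), Bmal1hep-/- (240) or both (353). Right, peak times in hours for the 353 genes called in both, of which 314 lie within 2 h of the diagonal on the 24 h circle, so that points in the corners are near it.

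Mean levels over the whole day were compared next, which asks whether liver Bmal1 deletion shifts muscle transcripts whatever the time. No gene passed the test singly: limma gave 0 at an adjusted p under 0.05 (smallest 0.115) and 907 at an unadjusted p under 0.05 (431 higher and 476 lower in Bmal1hep-/-) where 542 would be given by chance. The median 95% interval reached 0.12 to either side on the log2 scale. The 10 genes of smallest p, given as values and not as changes, were Mettl18 (0.30 ± 0.06, SE, log2), Insig1, which restrains sterol synthesis (0.31 ± 0.06), Atxn7l2 (0.22 ± 0.04), the GTPase Rab15 (-0.27), and Cxx1a (0.26). The others were the lipid droplet protein Plin3 (-0.25), the ribosomal gene Rps26 (0.27), the endothelial gene Tmem100 (0.48), Tmem243 (0.24) and Mtss1l (0.18). Without Bmal1hep-/- ZT4 replicate 1, 2 genes passed, 1 of them Atxn7l2 (0.24, adjusted p = 0.0166).

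Gene lists moved together with small medians. By limma's camera with a preset correlation, 14 of 50 lists passed at an adjusted p under 0.05, and none passed with an estimated correlation. Fatty acid oxidation genes were lower in Bmal1hep-/-, 23 of 24 of them (median -0.10, adjusted p = 4.62e-09, adjusted p = 0.402 with an estimated correlation), with 4 past the threshold adjusted over the list alone. Examples were the acyl-CoA dehydrogenase Acadvl (-0.18 ± 0.06), the electron transfer flavoprotein Etfa (-0.15 ± 0.05) and Hadhb of the trifunctional protein (-0.16 ± 0.05). PPAR and fasting targets were lower for 12 of 16 genes (median -0.098, 0.00857, adjusted p = 0.479 with an estimated correlation, 0 adjusted over the list alone), with -0.47 ± 0.15 for Pdk4, the kinase that turns off pyruvate dehydrogenase, and -0.29 ± 0.10 for Plin5. Genes of the TCA cycle were lower for 16 of 20 (median -0.056, 0.000667, adjusted p = 0.572 with an estimated correlation, 2 adjusted over the list alone: Mdh1, -0.20 ± 0.05, and Dlat, -0.14 ± 0.04). Genes of ketone body use and creatine were lower for 8 of 12 (median -0.062, 0.0129, adjusted p = 0.402 with an estimated correlation), with 3 adjusted over the list alone: the lactate and ketone body transporter Slc16a1 (-0.21 ± 0.06), Ampd3 and Acat1. The ketone and creatine list had an adjusted p of 0.0782 without Bmal1hep-/- ZT4 replicate 1. Without the 6 libraries that stood apart the TCA cycle (0.381, median -0.013) and ketone and creatine lists (0.146) no longer passed, while fatty acid oxidation (2.56e-05) and PPAR targets (0.017) did. The fatty acid oxidation and PPAR lists share Cpt1a, Slc25a20, Cd36, Fabp3 and Acot2, so they are not independent.

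Slow and oxidative fibre genes were lower in Bmal1hep-/- for 12 of 12 members (median -0.21, adjusted p = 0.000655, adjusted p = 0.572 with an estimated correlation), with 1 adjusted over the list alone, Myh2, the myosin of fast oxidative fibres (-0.38 ± 0.12). By time the median was below 0 at ZT0, ZT4, ZT16 and ZT20 and above 0 at ZT8 (0.22, 10 of 12 higher, adjusted p = 0.314) and at ZT12 (0.098, 7 of 12 higher, 0.918). Sarcomere and Z-disc genes were lower for 22 of 23 (median -0.14, 3.09e-06, adjusted p = 0.402 with an estimated correlation), with 5 adjusted over the list alone, among them the thin filament genes Lmod2 (-0.35 ± 0.12) and Lmod3 (-0.17 ± 0.06), and the medians at ZT8 and ZT12 were 0.02 and 0.0079. Cytosolic heat shock genes were lower for 16 of 19 (median -0.039, 0.022, adjusted p = 0.572 with an estimated correlation, 0 adjusted over the list alone), with medians above 0 at ZT8 (0.025), ZT12 (0.086) and ZT16 (0.0082). The heat shock call was kept in 27 of 36 fits without 1 library, with an adjusted p of 0.166 and a median of -0.025 without WT ZT16 replicate 3. Across the 36 libraries the means of the fatty acid oxidation and slow fibre lists correlated (Pearson's r = 0.567, permutation p = 0.00041, and Spearman's rho = 0.49, permutation p = 0.0028, the same after adjustment over 3 relations). The r was 0.387 without the 2 libraries farthest from the median, 0.597 within WT and 0.489 within Bmal1hep-/-. Without the 6 libraries that stood apart the sarcomere list had an adjusted p of 0.0992 (median -0.052), heat shock had 0.0992, and slow fibre 0.0285 with a median of -0.13.

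Cholesterol synthesis genes were higher in Bmal1hep-/- for 14 of 16 members (median 0.072, adjusted p = 0.0002, adjusted p = 0.402 with an estimated correlation), with Insig1 alone past the threshold adjusted over the list alone and 0.21 ± 0.08 for Sqle, squalene epoxidase. Interferon response genes were higher for 19 of 20 (median 0.10, 0.000134, adjusted p = 0.479 with an estimated correlation, 0 adjusted over the list alone), as in Isg15 (0.31 ± 0.12) and B2m (0.18 ± 0.07). Cytosolic ribosome genes were higher for 45 of 61 (median 0.047, 0.000667, adjusted p = 0.806 with an estimated correlation, 2 adjusted over the list alone: Rpl12, 0.28 ± 0.07, and Rpl17, 0.16 ± 0.05). Proteasome genes were higher for 23 of 30 (median 0.033, 0.00318, adjusted p = 0.714 with an estimated correlation, 1 adjusted over the list alone, Psmb2, 0.16 ± 0.04). The ribosome list did not pass without Bmal1hep-/- ZT8 replicate 2 (0.434, median 0.023), the median was 0.021 without Bmal1hep-/- ZT12 replicate 2, and the proteasome list had 0.0749 without that library. Without Bmal1hep-/- ZT12 replicate 3 the ribosome and proteasome medians were 0.073 and 0.053. Without the 6 libraries that stood apart the ribosome list (0.36, median -0.015) and the interferon list (0.235, median 0.03) did not pass, and the proteasome median was 0.056. At single times these lists also had medians below 0 that passed: -0.16 for interferon genes at ZT0, -0.097 and -0.21 for ribosome genes at ZT8 and ZT20 and -0.081 for proteasome genes at ZT20. In that order they had adjusted p = 0.601, 0.972, 0.605 and 0.669 with an estimated correlation.

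Lists of markers of other cell types passed in the mean over all times as well, though not with the same sign at each time. Fibro-adipogenic and tendon markers were lower in Bmal1hep-/- for 14 of 15 genes (median -0.19, adjusted p = 3.09e-06, adjusted p = 0.479 with an estimated correlation), with 4 adjusted over the list alone. These were genes of tendon: Tnmd (-0.93 ± 0.23), Comp (-0.94 ± 0.26), Thbs4 (-0.64 ± 0.18) and Fmod (-0.94 ± 0.30). At ZT20 the list's median was 0.20 (12 of 15 higher, adjusted p = 0.2). Adipocyte markers were higher for 8 of 8 (median 0.44, 0.0002, adjusted p = 0.479 with an estimated correlation), with Fabp4 (0.34 ± 0.11) past the threshold adjusted over the list alone. At ZT8 the adipocyte median was -0.81 (6 of 8 lower, adjusted p = 0.127). The adipocyte median was 0.26 without Bmal1hep-/- ZT4 replicate 1, and 0.16 (adjusted p = 0.0992) without the 6 libraries that stood apart. Hepatocyte markers were lower for 4 of 5 (median -0.79, 0.000415, adjusted p = 0.402 with an estimated correlation, 4 adjusted over the list alone), and the median was -0.53 without those 6 libraries, with medians above 0 at ZT0 and ZT4 (0.60 and 0.62). The respiratory chain lists had small medians over the whole day: -0.019 for complex I (adjusted p = 0.686), -0.032 for complexes II and III (0.155), -0.038 for complex IV (0.629) and -0.044 for ATP synthase (0.429).

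**Figure D3:**
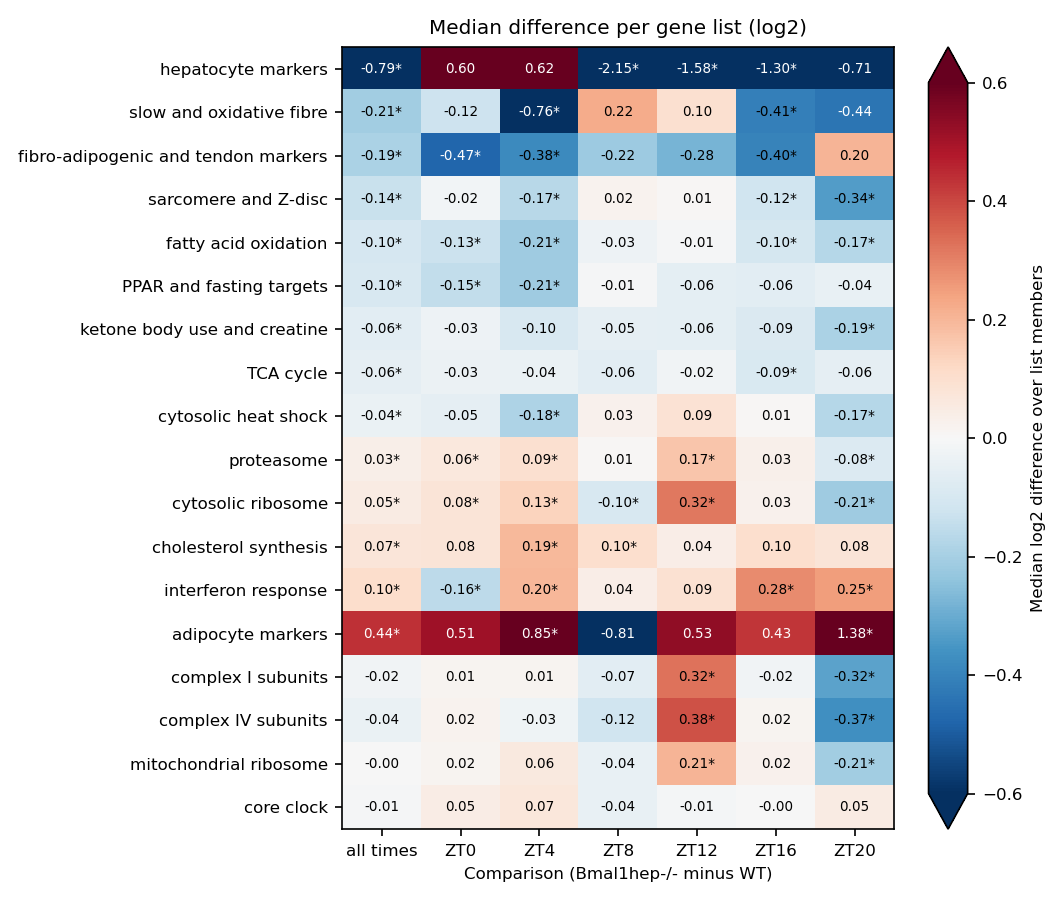
Median log2 difference, Bmal1hep-/- minus WT, over the members of each gene list (vertical) for all times together and for each zeitgeber time (horizontal), as colour (shown up to 0.6 in size) and number, with an asterisk for an adjusted p under 0.05 in camera with a preset correlation. The lists of complex I and complex IV are higher at ZT12 (0.32 and 0.38) and lower at ZT20 (-0.32 and -0.37) and near 0 over all times; the adjusted p with an estimated correlation was 0.824 at ZT12 and 0.587 at ZT20.

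Differences at each time of day were compared last. limma called 0 genes at every time, with 238 (ZT0), 982 (ZT4), 334 (ZT8), 786 (ZT12), 265 (ZT16) and 1364 (ZT20) at an unadjusted p under 0.05 and smallest adjusted p of 0.9998, 0.283, 0.9997, 0.686, 0.49 and 0.0961. The test of whether the genotype effect differed between times called 0 genes (503 at an unadjusted p under 0.05, smallest adjusted p 0.9). With array weights, whose estimate did not converge, 2098 genes passed at ZT8, 2068 at ZT12 and 2394 between times. Other splits of the samples gave up to 2250, 2557 and 3014 with such weights. With 3 libraries per group the median 95% interval reached 0.30 to either side on the log2 scale. The numbers of lists that passed from ZT0 to ZT20 were 8, 12, 3, 11, 11 and 18, and with an estimated correlation 0, 0, 1, 0, 1 and 0. Other splits of the same 6 libraries into 3 and 3 gave up to 14, 17, 13, 18, 16 and 20 lists.

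At ZT12 the mRNAs of mitochondrial respiration and of translation were higher in Bmal1hep-/-. Complex I subunits were higher for 34 of 36 (median 0.32, adjusted p = 7.93e-09), complex IV for 12 of 12 (0.38, 2.23e-05), ATP synthase for 15 of 16 (0.20, 0.00137) and complexes II and III for 13 of 14 (0.15, 0.0131), each with adjusted p = 0.824 with an estimated correlation. Mitochondrial ribosome genes were higher for 61 of 74 (0.21, 2.21e-10) and cytosolic ribosome genes for 59 of 61 (0.32, 2.26e-20). Both had adjusted p = 0.824 with an estimated correlation. Examples were Ndufb4 (0.63 ± 0.16) and Ndufs5 (0.78 ± 0.24) of complex I, Cox6c (0.46 ± 0.17) of complex IV, Mrpl51 (0.47 ± 0.13) and Rpl12 (0.60 ± 0.17). Proteasome genes (median 0.17, 2.32e-06), glycolysis genes (0.15, 0.0261) and fast glycolytic fibre genes (0.22, 0.000246) were also higher, each with adjusted p = 0.824 with an estimated correlation, and the mean of the fast fibre list was -0.066, of the other sign. Bmal1hep-/- ZT12 replicate 2, whose levels fell with transcript length, carried most of this, and without Bmal1hep-/- ZT12 replicate 3 the medians were larger, as in 0.49 for complex I, 0.60 for complex IV, 0.34 for ATP synthase, 0.24 for complexes II and III, 0.32 for the mitochondrial and 0.49 for the cytosolic ribosome, 0.27 for the proteasome, 0.25 for glycolysis and 0.35 for fast fibres. Without replicate 2, 3 lists passed, and the medians were 0.033 for complex I (adjusted p = 0.455), 0.083 for complex IV (0.358), 0.0091 for ATP synthase (0.9996), 0.035 for complexes II and III (0.89) and 0.043 for the mitochondrial ribosome (0.257). They were 0.064 for the proteasome (0.0564), 0.063 for glycolysis (0.695), 0.10 for fast fibres (0.142) and 0.13 for the cytosolic ribosome (0.000221). With a trend on transcript length removed from each library, a step chosen after the data were seen, 4 of the 6 respiratory chain and ribosome lists passed, with medians of 0.15 for complex I, 0.20 for complex IV, 0.13 for the mitochondrial and 0.17 for the cytosolic ribosome. Complexes II and III (0.069, adjusted p = 0.284), ATP synthase (0.12, 0.142) and glycolysis (0.097, 0.142) did not pass, and the proteasome median was 0.059. The 10 genes of smallest p, none past the threshold, were Tmem141 (0.71 ± 0.16), Rita1 (0.85), the DNA glycosylase Ogg1 (0.64), Inca1 (0.66), Ndufb4, the ribosomal genes Rpl36al (0.65) and Rpl36a (0.70), Smim11 (0.56), Atxn7l2 (0.41) and Gpx8 (0.72). Schwann cell markers were lower for 8 of 8 (median -0.61, 0.017, adjusted p = 0.824 with an estimated correlation), with a median of 0.26 and an adjusted p of 0.284 without WT ZT12 replicate 1 and a median of -1.01 without WT ZT12 replicate 2.

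At ZT20 the same lists were lower in Bmal1hep-/-, in libraries of which replicates 2 and 3 had levels that rose with transcript length. On the WT side, levels in WT ZT20 replicate 3 fell with length (Spearman's rho = -0.402). Complex I was lower for 35 of 36 (median -0.32, adjusted p = 4.58e-09, adjusted p = 0.587 with an estimated correlation), and complex IV for 12 of 12 (-0.37, 0.000141, adjusted p = 0.587 with an estimated correlation). ATP synthase was lower for 15 of 16 (-0.34, 2.65e-05), complexes II and III for 12 of 14 (-0.34, 0.000145, with 3 adjusted over the list alone) and the mitochondrial ribosome for 69 of 74 (-0.21, 5.57e-09). Each of these 5 lists had adjusted p = 0.587 with an estimated correlation. The cytosolic ribosome was lower for 53 of 61 (-0.21, 3.91e-05, adjusted p = 0.605 with an estimated correlation). With the length trend removed 5 of these 6 lists passed, with medians of -0.17 for complex I, -0.24 for complex IV, -0.26 for ATP synthase, -0.19 for complexes II and III and -0.13 for the mitochondrial ribosome, and the cytosolic ribosome did not (-0.06, adjusted p = 0.291). Over the 213 genes of the 6 lists the median went from -0.26 to -0.15, and at ZT12 from 0.27 to 0.15. Examples were Ndufa12 (-0.86 ± 0.26), Cox6b1 (-0.75 ± 0.28), Atp5g3 (-0.74 ± 0.27), Cyc1 (-0.55 ± 0.18) and Mrpl42 (-0.69 ± 0.20). Fatty acid oxidation genes were lower for 21 of 24 (-0.17, 0.00281, adjusted p = 0.59 with an estimated correlation). Sarcomere genes were lower for 20 of 23 (-0.34, 0.000315) and glycolysis genes for 16 of 17 (-0.16, 0.00281), both with adjusted p = 0.587 with an estimated correlation. In the same libraries adipocyte markers were higher for 8 of 8 (1.38, 0.00467, adjusted p = 0.59 with an estimated correlation). Macrophage markers were higher for 9 of 9 (0.65, 0.00179) and interferon genes for 17 of 20 (0.25, 0.00281), both with adjusted p = 0.587 with an estimated correlation.

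Leaving out Bmal1hep-/- ZT20 replicate 3, with its high adipocyte markers, brought the number of lists that passed from 18 to 6. The complex I list (0.00193, median -0.18), the mitochondrial ribosome (0.00193, -0.13) and ATP synthase (0.0288, -0.22) still passed without it. Complex IV (0.0606, -0.18), complexes II and III (0.104, -0.24), fatty acid oxidation (0.322, -0.081), sarcomere (0.214, -0.18), glycolysis (0.104), adipocyte (0.438, 0.58), macrophage (0.0983, 0.32) and interferon genes (0.369, 0.088) did not. Without WT ZT20 replicate 3 the cytosolic ribosome had an adjusted p of 0.0937 (median -0.092) and the medians of complex I and the mitochondrial ribosome were -0.18 and -0.11. Without Bmal1hep-/- ZT20 replicate 1 the medians were -0.54 for complex I, -0.64 for complex IV, -0.35 for the cytosolic ribosome and -0.25 for glycolysis, and without replicate 2 the adipocyte median was 2.19. Immediate early genes were lower for 14 of 17 (-0.35, 0.00179, adjusted p = 0.587 with an estimated correlation, 2 adjusted over the list alone: Ier3, -0.62 ± 0.17, and the phosphatase Dusp1, -0.72 ± 0.22), with a median of -0.13 without Bmal1hep-/- ZT20 replicate 2. Among the 10 single genes of smallest p were Mn1, a transcriptional coregulator (-0.67 ± 0.12, adjusted p = 0.0961), Fahd2a (-0.58), the kinase Stk17b (0.95), Fbxl15 (-1.12), the potassium channel Kcna5 (-0.56), the sodium channel subunit Scn4b (-0.35), Ube2l6 (0.75), the deacetylase Hdac5 (-0.44) and Tmem259 (-0.64). None of the genes listed passed, and each of them passed without Bmal1hep-/- ZT20 replicate 1 (Mn1 -0.78, adjusted p = 0.0143), as did 332 genes in all.

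At ZT4 genes of slow fibres and of fat use were lower in Bmal1hep-/-. Slow and oxidative fibre genes were lower for 12 of 12 (median -0.76, adjusted p = 1.44e-05, adjusted p = 0.67 with an estimated correlation), as in Myh2 (-0.78 ± 0.29) and Atp2a2, the slow fibre calcium pump (-0.85 ± 0.38), with a median of -0.42 without WT ZT4 replicate 2 and -1.20 without WT ZT4 replicate 1. Fatty acid oxidation genes were lower for 21 of 24 (-0.21, 2.2e-05, adjusted p = 0.67 with an estimated correlation), with a median of -0.12 without Bmal1hep-/- ZT4 replicate 2. Heat shock genes were lower for 18 of 19 (-0.18, 6.18e-05, adjusted p = 0.67 with an estimated correlation) and sarcomere genes for 19 of 23 (-0.17, 1.44e-05, adjusted p = 0.67 with an estimated correlation, 4 adjusted over the list alone, among them Ankrd1, a gene induced by stretch, -1.24 ± 0.30). Without the 6 libraries that stood apart the sarcomere list had an adjusted p of 0.0828, and its median was -0.39 without Bmal1hep-/- ZT4 replicate 3. PPAR targets were lower for 13 of 16 (-0.21, 0.0161, adjusted p = 0.67 with an estimated correlation), with Pdk4 at -1.11 ± 0.37. The list had an adjusted p of 0.448 and a median of -0.082 without Bmal1hep-/- ZT4 replicate 2, and a median of -0.36 without WT ZT4 replicate 1. Tendon and fibro-adipogenic markers were lower for 13 of 15 (-0.38, 0.000145, adjusted p = 0.726 with an estimated correlation), with 4 adjusted over the list alone. Their median was -0.21 without Bmal1hep-/- ZT4 replicate 2. Cytosolic ribosome genes were higher for 51 of 61 (0.13, 2.2e-05, adjusted p = 0.751 with an estimated correlation).

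Adipocyte markers at ZT4 were higher for 8 of 8 (0.85, adjusted p = 0.00191, adjusted p = 0.726 with an estimated correlation). Their median was 1.57 without Bmal1hep-/- ZT4 replicate 3. Without Bmal1hep-/- ZT4 replicate 1 it was -0.029 (0.98) and interferon genes, higher for 19 of 20 (0.20, 0.000468, adjusted p = 0.67 with an estimated correlation), had 0.135, with a median of 0.33 without Bmal1hep-/- ZT4 replicate 2. The 10 genes of smallest p, none past the threshold, were Irak1bp1 (-0.58), Cxx1a (0.66), Haus7 (0.62), Ciart (0.94 ± 0.22), Dym (0.44), Bub3 (0.40), Ankrd1, Synpo (-0.41), Hpcal1 (0.67) and the lipogenic gene Thrsp (1.18 ± 0.29). Without Bmal1hep-/- ZT4 replicate 1, 33 genes passed, among them Ciart (1.21, adjusted p = 0.0185), and without the 6 libraries that stood apart 115 did.

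Tendon, immune and glucocorticoid lists passed at ZT0 or ZT16. At ZT0 tendon and fibro-adipogenic markers were lower for 15 of 15 genes (median -0.47, adjusted p = 1.35e-07, adjusted p = 0.601 with an estimated correlation). Macrophage markers were lower for 9 of 9 (-0.45, 0.000464), fatty acid oxidation genes for 21 of 24 (-0.13, 5.01e-05) and interferon genes for 15 of 20 (-0.16, 0.000464). Each of these 4 lists had adjusted p = 0.601 with an estimated correlation. Without Bmal1hep-/- ZT0 replicate 2 the fatty acid oxidation list had 0.059 (median -0.073), the interferon median was -0.24 and 5 lists passed, and without Bmal1hep-/- ZT0 replicate 1 the interferon list had 0.303 (median -0.10). At ZT16 interferon genes were higher for 18 of 20 (0.28, 1.58e-08, adjusted p = 0.18 with an estimated correlation), as in Gbp2 (0.45 ± 0.16). Atrophy and FOXO targets were lower for 17 of 22 (-0.11, 0.000418, adjusted p = 0.0493 with an estimated correlation), as in the metallothionein gene Mt2 (-0.70 ± 0.33) and the glucocorticoid-induced factor Cebpd (-0.54 ± 0.19). Glucocorticoid targets were lower for 14 of 18 (-0.15, 0.000418, adjusted p = 0.0867 with an estimated correlation). The FOXO list's adjusted p with an estimated correlation was up to 0.296, without WT ZT16 replicate 1, and 19 lists passed with a preset correlation without that library. Genes among the 10 of smallest p at each of these times, none past the threshold, are given as values. At ZT0 they were Gemin2 (0.62 ± 0.16), Fgfbp3 (0.77), the MAP kinase phosphatase Dusp6 (-0.57), Irf2bp2 (0.46), B3gnt9 (-0.47), Gbp2 (-0.57), Plin3 (-0.48), Mtss1l (0.36), Shisa2 (0.36) and Adgrl1 (0.42). At ZT8 they were Fam32a (-0.58 ± 0.13), Alb (-2.65 ± 0.65), the mitochondrial import factor Grpel1 (-0.35), Znhit6 (-0.38), Mrps14 (-0.39), Prss23 (-0.30), Tceb1 (-0.34), Faim (-0.81), Gzmm (-0.57) and Vsig2 (0.58). At ZT16 they were the phosphate carrier Slc20a1 (0.61 ± 0.15), Aig1 (-0.77), Il10rb (0.56), Olfr856-ps1 (0.65), Prima1 (0.97), Cbr3 (-0.67), Kbtbd13 (-0.29), Ifi47 (0.70) and Snx11 (0.42).

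At ZT8 the list that passed with either correlation was that of hepatocyte markers, the mRNAs of plasma proteins made in liver. They were lower in Bmal1hep-/- for 5 of 5 genes (median -2.15, adjusted p = 1.67e-10, adjusted p = 0.0362 with an estimated correlation), with 4 adjusted over the list alone: Alb, the apolipoprotein genes Apoa1 (-2.09 ± 0.67) and Apoa2 (-2.95 ± 0.90), and Mup3 (-2.15 ± 0.65). WT ZT8 replicate 3 held Alb at 30.2 FPKM, and without it the list's median was -0.83 (0.000166). Without Bmal1hep-/- ZT8 replicate 2 the adjusted p was 0.823 with an estimated correlation. The list was also lower at ZT12 (-1.58, 0.0147, adjusted p = 0.824 with an estimated correlation) and at ZT16 (-1.30, 5.62e-06, adjusted p = 0.138 with an estimated correlation), and the ZT12 call had 0.114 without Bmal1hep-/- ZT12 replicate 1. At ZT0 and ZT4 its median was 0.60 and 0.62 and it did not pass (0.175 and 0.19). Mean Alb in WT was 0.121, 0.235, 11.9, 3.68, 4.01 and 1.96 FPKM from ZT0 to ZT20, and in Bmal1hep-/- 1.92, 1.93, 0.247, 0.653, 0.457 and 0.221 FPKM. The Bmal1hep-/- libraries ran from 0.165 to 5.29 FPKM at ZT0 and from 0.136 to 4.57 FPKM at ZT4, the highest being replicate 2 at ZT0 and replicate 3 at ZT4.

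**Figure D4:**
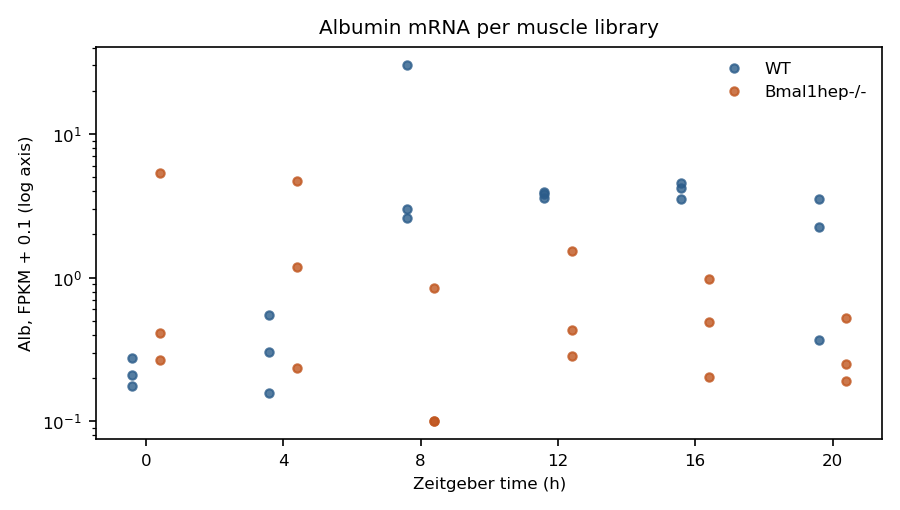
Alb mRNA per muscle library, in FPKM with 0.1 added, on a log axis, against zeitgeber time in hours, with a point per library. WT ZT8 replicate 3 stands at 30.2 FPKM, and the means are higher in WT from ZT8 (11.9 against 0.247 FPKM) to ZT20 and lower at ZT0 and ZT4.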

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

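The tests chosen only after the result was seen are those with the transcript length trend removed, without the 6 libraries that stood apart, the leave-one-out fits of lists, and the block for lists among rhythmic genes. The counts of 0 genes over all times, at each time, between times and for the difference in rhythm stayed at 0 with a pseudocount of 0.1, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization and the length trend removed. In limma as reported, 907, 238, 982, 334, 786, 265, 1364, 503 and 435 genes had an unadjusted p under 0.05. Under these 5 settings rhythmic genes numbered 517 to 776 in WT and 420 to 655 in Bmal1hep-/-. Without a filter on level 1 gene passed at ZT0, 2 at ZT8, 1 at ZT16 and 1 between times. With limma array weights, whose estimate did not converge in the fit of group means, 186 genes passed over all times, 10 at ZT4, 2098 at ZT8, 2068 at ZT12, 1 at ZT16 and 2394 between times, and 1388 were rhythmic in WT. The largest weight, 41.1, fell on Bmal1hep-/- ZT8 replicate 3, and among 19 other splits the weights gave up to 1347 genes over all times, 2250 at ZT8, 2557 at ZT12 and 3014 between times.

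With an estimated correlation the lists numbered 0 over all times, 0 at ZT0, 0 at ZT4, 1 at ZT8, 0 at ZT12, 1 at ZT16 and 0 at ZT20. With only the 6 libraries of that time 4 genes passed at ZT4 and 4 at ZT16. With time as a factor 334 genes were rhythmic in WT and 335 in Bmal1hep-/-, and with only the 18 libraries of that genotype 985 and 320. Selection by BIC, which does not control false calls, gave 2419 and 2361. It chose a model with unlike rhythms for 1029 genes, of which 59 had a rhythm in both genotypes. With an amplitude of at least 0.25 there were 376 and 360. At an unadjusted p under 0.01, 78 genes differed in rhythm. With the length trend removed 1 list passed at ZT8. Without the 6 libraries that stood apart 115 genes passed at ZT4, 383 were rhythmic in Bmal1hep-/- (318 of them among the 593), and 8, 5 and 7 lists passed at ZT8, ZT12 and ZT20. A minimum amplitude lowers the counts by construction, and the cause of the other changes was not tested. The fits on the 18 libraries of 1 genotype held fewer libraries and also took the spread from that genotype alone. Root mean square deviations from the group means were 0.23 in WT and 0.29 in Bmal1hep-/- on the log2 scale.

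With the replicate number as a block 672 genes were rhythmic in WT and 581 in Bmal1hep-/-, 15 lists passed over all times, and the counts of 0 genes stayed at 0. No pairing of animals by number showed on average: deviations correlated by 0.0049 for the same number and -0.0022 for others. These averages run over all times. For the 18 pairs of the same number at the same time the correlation ran from -0.228 to 0.178, with 3 over 0.1. A pairing within a time is therefore not excluded.

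Leaving out 1 library at a time gave 0 to 2 genes over all times (2 without Bmal1hep-/- ZT4 replicate 1), 0 to 33 at ZT4 (33 without the same library), 0 to 332 at ZT20 (332 without Bmal1hep-/- ZT20 replicate 1) and 0 to 0 at ZT0, ZT8, ZT12, ZT16 and between times. A group left with 2 libraries was assumed to vary like the others. Rhythmic genes ran from 553 to 720 in WT and from 464 to 839 in Bmal1hep-/-, differences in rhythm from 0 to 1 (without WT ZT16 replicate 3) and the amplitude ratio from -0.072 to 0.083, the latter without Bmal1hep-/- ZT8 replicate 1. Lists ran from 12 to 18 over all times, 5 to 11 at ZT0 (5 without Bmal1hep-/- ZT0 replicate 2), 8 to 15 at ZT4, 1 to 6 at ZT8 (1 without WT ZT8 replicate 2, 5 without WT ZT8 replicate 3, 6 without Bmal1hep-/- ZT8 replicate 1 or 2). They ran from 3 to 12 at ZT12 (3 without Bmal1hep-/- ZT12 replicate 2), 10 to 19 at ZT16 (19 without WT ZT16 replicate 1) and 6 to 25 at ZT20 (6 without Bmal1hep-/- ZT20 replicate 3). Lists among rhythmic genes ran from 5 to 8 in WT and from 5 to 8 in Bmal1hep-/-. Of values for single named genes under the alternatives set before the data were examined, 52 genotype differences, 1 rhythm and 1 difference in rhythm came past the threshold, and 1 rhythm no longer passed. Relative depth spanned 57.9% to 100%. Since the absolute depth is unknown, the counting error of genes of low FPKM could not be given, and genes under 1 FPKM were left out.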

Other observations

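The tests chosen only after the result was seen are the length trend, the splits for lists at single times and for the ZT12 median, the single Bmal1hep-/- or WT library, both tests of hepatocyte mRNAs, both tests of PPAR targets and the values without the 6 libraries that stood apart. The other counts over splits of the samples, the shared rhythm and the genotype effect at ZT20 were chosen before. Lists not yet described passed at single times. At ZT16 sarcomere genes were lower for 22 of 23 (median -0.12, adjusted p = 5.45e-05, adjusted p = 0.427 with an estimated correlation), with -0.048 without Bmal1hep-/- ZT16 replicate 3. Slow fibre genes (12 of 12 lower, -0.41, 0.000603), TCA cycle genes (18 of 20, -0.092, 7.92e-05), fatty acid oxidation genes (22 of 24, -0.10, 0.000185) and tendon markers (14 of 15, -0.40, 0.000118) were lower, each with adjusted p = 0.544 with an estimated correlation. Endothelial markers were higher (9 of 10, 0.15, 0.00879), with adjusted p = 0.544 with an estimated correlation. Macrophage markers were lower for 7 of 9 (-0.38, 0.0475, adjusted p = 0.765 with an estimated correlation). Without WT ZT16 replicate 3 slow fibre genes had 0.241 (median -0.24), the TCA cycle 0.0938 (-0.07) and fatty acid oxidation 0.134 (-0.059, against -0.17 without Bmal1hep-/- ZT16 replicate 2), and the slow fibre median was -0.22 without Bmal1hep-/- ZT16 replicate 1. Tendon markers had 0.0677 (-0.21) without Bmal1hep-/- ZT16 replicate 1, endothelial markers 0.059 without Bmal1hep-/- ZT16 replicate 3 and macrophage markers 0.757 (-0.12) without WT ZT16 replicate 2. The macrophage median was -0.091 without Bmal1hep-/- ZT16 replicate 2.

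Protein turnover and sterol lists passed at other times. At ZT0 proteasome genes (26 of 30 higher, 0.065, adjusted p = 0.0128, adjusted p = 0.86 with an estimated correlation) were higher. So were cytosolic ribosome genes (49 of 61, 0.078, 0.0413, adjusted p = 0.898 with an estimated correlation) and fast fibre genes (12 of 14, 0.14, 0.0412, adjusted p = 0.829 with an estimated correlation). PPAR targets were lower (14 of 16, -0.15, 0.0146, adjusted p = 0.601 with an estimated correlation). Proteasome and ribosome genes had 0.472 (median 0.023) and 0.632 (-0.0098) without WT ZT0 replicate 1. The proteasome median was 0.11 without WT ZT0 replicate 3 and the ribosome median 0.14 without WT ZT0 replicate 2. Fast fibre genes had 0.344 (0.098) without WT ZT0 replicate 2 and PPAR targets 0.165 (-0.073) without Bmal1hep-/- ZT0 replicate 2. At ZT4 cholesterol synthesis genes were higher (10 of 16, 0.19, 0.026, adjusted p = 0.67 with an estimated correlation), with 0.116 without Bmal1hep-/- ZT4 replicate 1. Proteasome (22 of 30, 0.094, 0.0337) and fast fibre genes (11 of 14, 0.17, 0.0447) were higher, both with adjusted p = 0.751 with an estimated correlation. They had 0.448 (median 0.043) and 0.334 (0.10) without Bmal1hep-/- ZT4 replicate 2, and the proteasome median was 0.042 without Bmal1hep-/- ZT4 replicate 3. Without Bmal1hep-/- ZT4 replicate 1 the medians were 0.14 and 0.27. At ZT8 cholesterol synthesis genes were higher for 14 of 16 (0.10, 0.0175, adjusted p = 0.685 with an estimated correlation). Cytosolic ribosome genes were lower for 47 of 61 (-0.097, 0.016, adjusted p = 0.972 with an estimated correlation). The cholesterol and ribosome lists had 0.0976 and 0.85 without Bmal1hep-/- ZT8 replicate 3, with a ribosome median of 0.03 without Bmal1hep-/- ZT8 replicate 1 and -0.31 without Bmal1hep-/- ZT8 replicate 2. Without the 6 libraries that stood apart the ribosome list had a median of -0.25 (adjusted p = 1.06e-13) and the cholesterol list 0.17 (0.0267). At ZT20 ketone and creatine (11 of 12, -0.19, 0.0162, adjusted p = 0.587 with an estimated correlation) and fast fibre genes (13 of 14, -0.19, 0.0173, adjusted p = 0.602 with an estimated correlation) were lower. So were heat shock (14 of 19, -0.17, 0.0476, adjusted p = 0.602 with an estimated correlation) and proteasome genes (24 of 30, -0.081, 0.0317, adjusted p = 0.669 with an estimated correlation). ER chaperones were higher (14 of 18, 0.11, 0.0278, adjusted p = 0.587 with an estimated correlation). Without Bmal1hep-/- ZT20 replicate 3 ketone genes had 0.303 (median -0.15), proteasome genes 0.956 (-0.038) and ER chaperones 0.369 (0.058), and the heat shock median was -0.084. Without WT ZT20 replicate 3 fast fibre genes had 0.466 (-0.05) and heat shock genes 0.353 (-0.13), and the proteasome median was -0.027. The ER median was 0.045 without WT ZT20 replicate 1, and without Bmal1hep-/- ZT20 replicate 1 it was 0.17 and the proteasome median -0.13. The fast fibre median was -0.30 without WT ZT20 replicate 2. With the length trend removed the proteasome (0.819, -0.0058) and fast fibre lists (0.151, -0.076) did not pass.

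Respiratory chain and ribosomal mRNAs, 213 genes, had a median difference of 0.27 at ZT12 (194 higher) and -0.26 at ZT20 (196 lower). They are short (median 1260 nt against 3361 nt). Across libraries their mean went with the length trend of other genes (Pearson's r = -0.894, Spearman's rho = -0.911, permutation p = 1e-05, the smallest possible, 1.5e-05 after adjustment over 3 relations). The r was -0.855 without the 2 farthest libraries, -0.867 within WT and -0.931 within Bmal1hep-/-. Removing the trend left 56.15% and 58.72% of the medians, and 4 and 5 of the 6 lists passed as the medians fell. Lengths were those of the longest transcript per symbol, perhaps of another build, so the step may remove too little. These values therefore cannot exclude the trend as the whole cause, and part of the pattern may come from it. A single library may account for most of ZT12, where 26.55% (0.071) was left without Bmal1hep-/- ZT12 replicate 2 and at least 93.88% was left without 1 WT library. At ZT20 at least 66.92% (-0.17) was left without 1 Bmal1hep-/- library (replicate 3) and 57.34% (-0.15) without 1 WT library (replicate 3), which argues against a single library as the main source there. An effect of genotype stays open: 3 of 10 splits at ZT12 (another gave -0.32) and 3 of 10 at ZT20 (another gave -0.35) had a median as large, and the bound set beforehand against it was wrong, since an effect smaller than the spread between libraries is also outdone by other splits.

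Hepatocyte mRNAs were high in the same libraries. Alb went with the mean of the other markers (Spearman's rho = 0.894 and Pearson's r = 0.927, permutation p = 1e-05, the smallest possible, 1.5e-05 after adjustment over 3 relations), with r = 0.93 and rho = 0.875 without the 2 farthest libraries, and r = 0.936 within WT and 0.888 within Bmal1hep-/-. In WT ZT8 replicate 3, Apoa2 stood at 118.5, Apoa1 at 38.9, Alb at 30.2 and Ttr at 22.1 FPKM. Liver RNA in some libraries may be the source, a hypothesis formed from these data. The correlation cannot tell it from another source that the markers share. An effect of genotype at every time stays open. At ZT0 mean Alb in WT was 0.0628 times that in Bmal1hep-/-, but the latter mean rests on Bmal1hep-/- ZT0 replicate 2 (5.29 FPKM), and the libraries overlapped (0.0773 to 0.174 in WT, from 0.165 in Bmal1hep-/-). At ZT4 it was 0.122 times that in Bmal1hep-/-, again with overlap (0.0576 to 0.445 FPKM in WT, 0.136 to 4.57 in Bmal1hep-/-). At ZT8, ZT12 and ZT16 each WT library lay above each Bmal1hep-/- library. The lowest WT values were 2.5, 3.5 and 3.45 FPKM, and the highest Bmal1hep-/- values 0.742, 1.44 and 0.877 FPKM. At ZT20 they overlapped (0.267 to 3.44 FPKM in WT, 0.0904 to 0.422 in Bmal1hep-/-).

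Rhythms called in 1 genotype only, 541 genes, were as many or more in 31 of 100 swaps of genotype within time (highest other 1404), so chance is not excluded. When 1 rhythm was simulated for both genotypes, with 1346 rhythmic genes, 4 of 20 draws gave at least as many (median 448, from 332 to 3099). A shared rhythm with a threshold applied to each genotype may thus be the source. In these draws a median of 443.5 genes was called in both genotypes, more than the 353 of the real libraries. The simulated rhythms were those fitted in genes chosen as rhythmic, so the draws may call too many genes in both. Swaps of genotype within time gave 308 to 406 genes called in both, a range that holds the real 353. A difference of rhythm in some genes stays open.

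A hypothesis that PPAR and fasting targets cycle more strongly in Bmal1hep-/- was formed after the 50 lists were seen. Their median log2 amplitude ratio was 0.74 over 16 genes, and 1 of 100 swaps gave one as large in size, the real one (permutation p = 0.01, the smallest possible). The other swaps ran from -0.68 to 0.65. Adjusted over the 50 lists p was 0.429, and 45 of 100 draws held some list as far from 0 as this one (2.3 SD, highest other 3.81), so the choice of 1 list among all may account for it. The ratio was 0.28 without the 6 libraries that stood apart and ran from 0.50 (without WT ZT12 replicate 3) to 0.83 without 1 library.

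Other splits of the samples were counted for each genome-wide result. Rhythmic genes outnumbered those of permuted times: of 100 permutations, 1, the real one, gave 654 genes in WT (highest other 160), and 1 gave 593 in Bmal1hep-/- (547). This bears on the number of genes and not on single calls. In the simulated data false calls made up 31.9% of calls for rhythms in WT and 2.12% in Bmal1hep-/-. The medians over draws were 2.1% and 0.639%, and single draws reached 88.8% and 8.65%. Residuals were shuffled over both genotypes there, so these rates do not compare WT with Bmal1hep-/-. Swapping genotype within time did not exclude chance for the 907 genes over all times (22 of 100 as large, highest other 2973), the 503 between times (36, 2333), the 435 in rhythm difference (45, 2913) or the 14 lists (23, 21). Single times have 10 splits, too few for a share under 0.05: 238 genes at ZT0 (2 as large, highest other 269), 982 at ZT4 (1, 977), 334 at ZT8 (8, 2128), 786 at ZT12 (4, 2080), 265 at ZT16 (3, 461) and 1364 at ZT20 (3, 2067). For lists the real counts were 8 at ZT0 (4 of 10 splits had as many, highest other 14), 12 at ZT4 (3, 17), 3 at ZT8 (10, 13), 11 at ZT12 (9, 18), 11 at ZT16 (5, 16) and 18 at ZT20 (4, 20). Splits that gave several times the real count point to a structure of the samples, and its cause was not tested.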
